A study of Mus musculus with 24 samples.

How the data were processed

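RNA from kidney and gastrocnemius of 12 male mice, 6 WT and 6 KO, had been sequenced as 24 polyA-selected libraries. The deposited values are raw counts per Ensembl gene, not normalized; per the submitters' processing notes, the tools were STAR 2.7.11b and featureCounts 2.0.6 on the GRCm39 build, with no annotation release, strand setting or pair setting stated. The table holds 57010 gene identifiers, of which 20832 have no count in any library. Symbols came from a GENCODE annotation of the GRCm38 build, an earlier build than the one of the files; 52029 identifiers, with 98.39% of counts, have a symbol, and 1 identifier without a symbol takes 0.411 to 2.59% of the counts of a library. Among counts from 1 to 10, 73.1 to 81.8% are even, which is the pattern left when both mates of a read pair are counted, so the number of fragments is uncertain.

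Total counts were 29032219 to 37649359 in kidney and 36548574 to 54170941 in muscle libraries. A count of 0 allows up to 3 counts, or 0.0554 to 0.103 CPM in a single library, and up to 6 counts, or 0.111 to 0.207 CPM, if both mates of each pair were counted. This floor, taken over the group where a fold is given, covers counting error only, since reads without molecular identifiers are not independent molecules.

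Each tissue was fitted by itself in R 4.3.3 with edgeR 4.0.16: filterByExpr by genotype (minimum count 10, minimum total 15), TMM factors, robust dispersion trend and quasi-likelihood F-test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The difference between tissues was the interaction of tissue and genotype in 1 fit of all 24 libraries, without a block. Overlap was counted among the genes tested in both tissues, against the number that independent lists of the same sizes would share. Lists with at least 4 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of the tissue, and again with an estimated correlation; 42 lists were tested in kidney and 37 in muscle. At the preset correlation 16 and 13 lists passed, and with an estimated correlation 0 passed in either tissue. Kl was also tested by a two-sided exact permutation test of the mean CPM.

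The groups, tests, gene lists, naming rule and the alternatives listed next were fixed before the data were examined. Genes named were Kl; the 8 largest rises and 8 largest falls per tissue with an adjusted p below 0.05, a mean of at least 2 CPM, groups that do not overlap and a symbol that is not a predicted, clone or immunoglobulin segment name; up to 4 members with the smallest p of each list described; the 6 largest interactions per direction; and for the overlap the 5 genes per direction with the smallest p. For the FGF and ERK targets all 5 passed members were given, 1 more than the rule allows. Trim63, Fbxo32, Cyp24a1, Ighm, Cd3e, Igkc and Jchain were chosen after their values were seen.

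Those alternatives were DESeq2 size factors and upper-quartile factors within edgeR, no filter, a filter of 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom with quality weights, a fold of at least 2, 1 fit of all libraries, a replicate block, a threshold of 0.01 for the overlap, and leaving out each library in turn. Alternatives added after seeing the data were plain library-size scaling, counts divided by 2, removal of each library's trend over transcript length, and leaving out pairs of libraries. The muscle pair, WT 1 and WT 5, lies apart on the first principal components; of the kidney pair, WT 4 lies apart on the second component (-73.6), and KO 3 was added before its place there (-38.7, the next lowest) had been looked up.

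Whether replicate numbers pair the samples was checked by correlating residuals. WT and KO libraries of 1 number had r from -0.0944 to 0.118 in kidney and from -0.217 to 0.217 in muscle. Above 0.1 were 1 of 6 in kidney and 3 of 6 in muscle, each closest to its own number. WT and KO mice are different animals, so these libraries were not treated as pairs, and the replicate block is among the alternatives. Kidney and muscle libraries that carry the same animal number had r from -0.0608 to 0.273, with 4 of 12 above 0.1. Among the 6 animals of a genotype, 7 of 12 kidneys were closest to the muscle of their own number, more than random matching would give. Every KO kidney was among them. The main interaction fit leaves this link out, and the animal is a block only among the alternatives. The animal numbers of WT and KO mice lie in separate ranges and no litter, cohort or date is given, so a difference between cohorts cannot be told apart from genotype.

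The fits were tested on simulated data with 1 spread per gene, estimated from the data and equal in all groups of a fit. Simulated changes of 1.5, 2 and 4-fold were recovered in 43.3, 82.1 and 97.0% of cases in kidney, 4.48, 47.8 and 97.0% in muscle and 4.48, 35.8 and 92.4% for the interaction, with 3.90, 5.71 and 2.22% false calls. In each simulation 67, 67 and 66 genes were changed at these folds, of 17246 tested in kidney, where 36.5% of real genes passed. The adjusted threshold was thus stricter in the simulated kidney, and these rates need not hold for the real data. Of 40 unchanged simulated lists per tissue, 0 were called. Genes were drawn independently, so this could not show false calls that arise when members of a list vary together. Lists with fewer than 4 tested members were left out, and no library was excluded.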

Results

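Messenger RNA was sequenced from the kidney and the gastrocnemius, a fast-twitch muscle of the calf, of male C57BL/6J mice aged 8 weeks. The mice were wild type (WT) or lacked α-klotho (KO), the membrane protein encoded by Kl that serves as co-receptor for the phosphate-regulating hormone FGF23. The 24 libraries formed 4 groups of 6, one for each tissue and genotype, and each of the 12 animals gave both tissues. Total counts ran from 29032219 to 37649359 per kidney library and from 36548574 to 54170941 per muscle library. Levels are given as CPM (counts divided by the TMM-scaled library size, in the usual unit), as mean ± SD with n = 6 per group, and fold changes are KO against WT.

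Kl itself was examined first, to check the genotype labels. In kidney, Kl (ENSMUSG00000058488) stood at 611 ± 151 CPM in WT and 0.520 ± 0.251 CPM in KO libraries (SD, n = 6 per group). Raw Kl counts were 14092 to 29384 in every WT kidney and 8 to 33 in every KO kidney. The difference passed in the edgeR quasi-likelihood test (log2 fold change -10.20, adjusted p = 7.89e-11), and a two-sided exact permutation test over 924 arrangements gave p = 0.00216, the smallest these groups allow. Muscle held far less Kl, at 0.812 ± 0.25 CPM in WT (26 to 52 counts) and 0.108 ± 0.0701 CPM in KO (0 to 8 counts). That fall passed as well in edgeR (log2 fold change -2.86, adjusted p = 0.00556; exact permutation p = 0.00216). No library went against its label, although the labels do not say which part of Kl the allele removes.

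**Figure D1:**
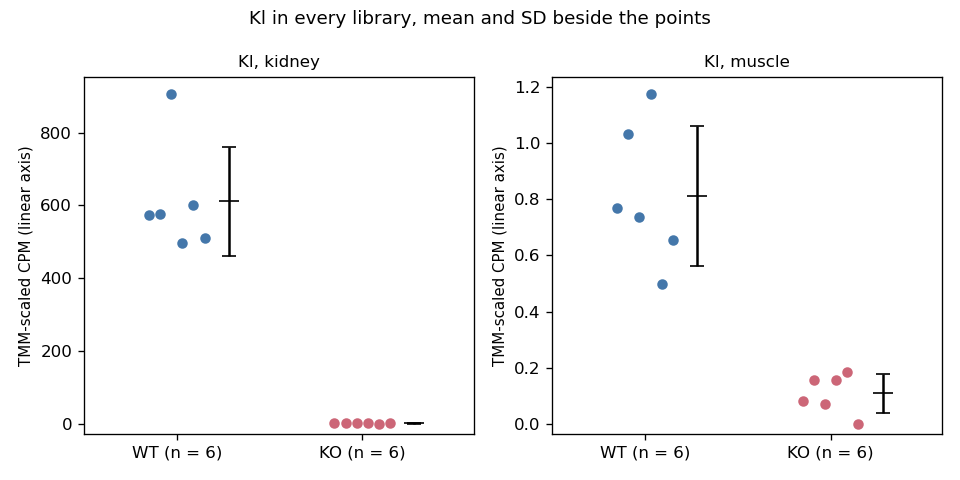
Kl in each library, in TMM-scaled CPM on linear axes, for kidney (left) and muscle (right), with the mean and SD of each group beside its 6 points. KO kidneys average 0.520 CPM against 611 CPM in WT.

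The kidney comparison asks which transcripts change in the organ with most Kl when the gene is lost. Cyp27b1, the renal hydroxylase that makes active vitamin D, rose 17.9-fold, from 5.80 ± 3.08 to 104 ± 45.5 CPM (log2 fold change 4.16). Its adjusted p = 0.00013 came from edgeR quasi-likelihood with Benjamini-Hochberg adjustment, as throughout this comparison. Gc, which encodes the vitamin D binding protein, rose from 29.5 ± 13.1 to 215 ± 67.6 CPM, and the prolactin receptor Prlr from 24.4 ± 11.8 to 143 ± 60.3 CPM. The organic anion transporter genes Slco1a1 and Slc22a7 were nearly absent from KO kidneys, Slco1a1 falling from 112 ± 70 to 0.268 ± 0.157 CPM (log2 fold change -8.68, adjusted p = 3.51e-05) and Slc22a7 from 263 ± 111 to 0.705 ± 0.241 CPM (-8.51, adjusted p = 3.61e-07). Sec14l3, a lipid-binding protein, went from 10.3 ± 3.26 CPM to 0 counts in all 6 KO kidneys, at least 749-fold lower against a floor of 3 counts over the KO group (adjusted p = 5.78e-07). If both mates of each pair were counted, the floor would be 6 counts and the bound 374-fold.

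Further large rises in kidney were those of Ugt1a2 (log2 fold change 5.41), Ugt1a10 (4.46, and 5.11 without kidney WT 4), Gsta1 (3.57), the efflux pump Abcc3 (2.99) and Marc1 (2.91). The remaining large falls were those of Cyp2a4 (-7.16), Akr1c18, a steroid dehydrogenase (-6.69), Mpped1 (-6.42) and Ugt2b38 (-5.77). The rule that picked these genes admitted only those whose WT and KO libraries do not overlap. Reads of Ugt1a2 and Ugt1a10, which share exons, and of Gsta1, Cyp2a4 and Ugt2b38, which have close relatives, could be split between copies, so the levels of these genes are uncertain.

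Mineral-handling genes moved in both directions. Of 11 phosphate transport genes, 2 rose and 2 fell (adjusted over the list alone, 2 rose and 4 fell). Slc34a1, the main sodium-phosphate cotransporter of the proximal tubule, fell from 4129 ± 1460 to 2208 ± 402 CPM (edgeR adjusted p = 0.0035). Its scaffold gene Slc9a3r1 fell from 322 ± 48.3 to 202 ± 31.7 CPM. Slc20a1 rose by 0.47 and the FGF receptor Fgfr1 by 0.27 on the log2 scale. Besides Cyp27b1, 4 of 10 vitamin D genes fell (adjusted over the list alone, 1 rose and 6 fell). These included the vitamin D receptor Vdr (-0.66), the parathyroid hormone receptor Pth1r (-0.74) and Pdia3 (-0.81). Of 14 calcium and magnesium transport genes, 3 rose and 2 fell (adjusted over the list alone, 3 and 2). Pvalb fell from 35.7 ± 9.98 to 5.96 ± 3.29 CPM, Cnnm2 fell (-0.73), and the channel Trpm7 rose (0.47). Of 15 FGF and ERK feedback targets, 4 fell and 1 rose (adjusted over the list alone, 4 and 1). Etv5 (-1.16), Etv4 (-1.41), Phlda1 (-0.66) and Dusp6 (-0.55) fell, and Junb rose (1.04). None of these 4 lists passed camera as a whole (adjusted p = 0.525, 0.288, 0.987 and 0.903 in that order). Over all genes tested in kidney 36.5% passed, rises and falls together, so a count of both near that share says little about a list. Fgfr1 and Trpm7 no longer passed in edgeR once each library's trend over transcript length was taken out (adjusted p = 0.277 and 0.178), nor Fgfr1 with no filter on low counts (0.0516), and Vdr and Phlda1 did not pass with plain library-size scaling (adjusted p = 0.052 and 0.086).

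Genes with a sex difference in the mouse kidney included, among the lists tested in kidney, the one with the largest median change. All 13 male-biased genes fell (adjusted over the list alone, also 13), with a median log2 fold change of -2.60. Camera gave adjusted p = 6.13e-19, and adjusted p = 0.0793 with an estimated correlation. The androgen-regulated kidney protein Kap fell from 39500 ± 13710 to 6514 ± 632 CPM and the oxysterol hydroxylase Cyp7b1 from 175 ± 76.9 to 6.61 ± 0.645 CPM. Odc1, which makes putrescine, fell from 499 ± 142 to 154 ± 16.6 CPM and Gusb from 38.8 ± 3.58 to 21.2 ± 2.32 CPM. Of 6 female-biased genes, 3 rose and 1 fell (adjusted over the list alone, 4 and 1). Camera gave it adjusted p = 0.00247, and adjusted p = 0.421 with an estimated correlation. Abcc3 and Prlr were joined by Cyp4a14, which rose from 194 ± 88.1 to 644 ± 245 CPM. Slco1a6 fell (-0.59, edgeR adjusted p = 0.0338), a call that was lost without any 1 of kidney WT 1, 3 or 6 or KO 1, 3, 4 or 6 (highest adjusted p = 0.0874).

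Nephron segment markers were examined next. Of 20 proximal tubule markers, 13 fell and 0 rose (adjusted over the list alone, 14 fell). The camera test gave adjusted p = 8.28e-07, and adjusted p = 0.479 with an estimated correlation. The urate transporter Slc22a12 fell from 1344 ± 283 to 571 ± 97.6 CPM and Slc17a3 from 402 ± 104 to 79.9 ± 35.1 CPM. Ggt1 fell from 1245 ± 313 to 537 ± 80.9 CPM, and Miox from 1563 ± 535 to 597 ± 76.2 CPM. Among 10 thick ascending limb markers 1 fell, Cldn10 (-0.50; adjusted over the list alone, also 1). Of 10 distal convoluted tubule markers Sgk1 rose (1.18) and Pvalb fell (adjusted over the list alone, 1 and 1). Of 12 podocyte markers Thsd7a, Wt1 and Mafb rose (0.70, 0.82 and 0.38; adjusted over the list alone, 3). Camera adjusted p for these last 3 lists was 0.876, 0.987 and 0.398. In edgeR, Cldn10 did not pass with plain library-size scaling (adjusted p = 0.217), nor Thsd7a with the trend over transcript length removed (adjusted p = 0.141).

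Most tested members of the oxidative phosphorylation, mitochondrially encoded, TCA cycle and proteasome lists fell in the KO kidney. Of 78 nuclear-encoded oxidative phosphorylation genes, 76 fell (adjusted over the list alone, 76), with a median log2 fold change of -0.67. Camera gave adjusted p = 8.83e-32, and adjusted p = 0.421 with an estimated correlation. Ndufa1 fell from 177 ± 22.4 to 82.6 ± 11.1 CPM, Ndufv3 from 206 ± 36.3 to 102 ± 9.44 CPM and Sdhc from 390 ± 36.9 to 229 ± 16.8 CPM. Of 13 mitochondrially encoded mRNAs, 10 fell (adjusted over the list alone, 11; camera adjusted p = 1.7e-06, and adjusted p = 0.479 with an estimated correlation), such as mt-Co3 (-0.96) and mt-Nd2 (-0.94). Of 19 TCA cycle genes, 15 fell (adjusted over the list alone, 15; camera adjusted p = 2.45e-05, and adjusted p = 0.479 with an estimated correlation), and Mdh2 went from 465 ± 60.7 to 299 ± 9.79 CPM. Of 31 proteasome subunits, 29 fell (adjusted over the list alone, 29; camera adjusted p = 9.8e-10, and adjusted p = 0.485 with an estimated correlation), with Psmc4 at -0.79 and Psmb5 at -0.89. Across genes, the kidney log2 fold change rose with transcript length (Spearman rho 0.315 over 16990 genes, and 0.495 over the 10207 genes above 8 CPM; genes are not independent replicates), from a median of -0.25 in the shortest of 5 equal groups to 0.30 in the longest. The labels give no RNA integrity values. Many members of these groups have short transcripts, yet the 70 ribosomal protein genes, also short, had a median of 0.12 with 1 fall (Rpl13a, -0.57) and 1 rise (Rps4x, 0.42), against 1 and 0 adjusted over the list alone (camera adjusted p = 0.194).

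**Figure D2:**
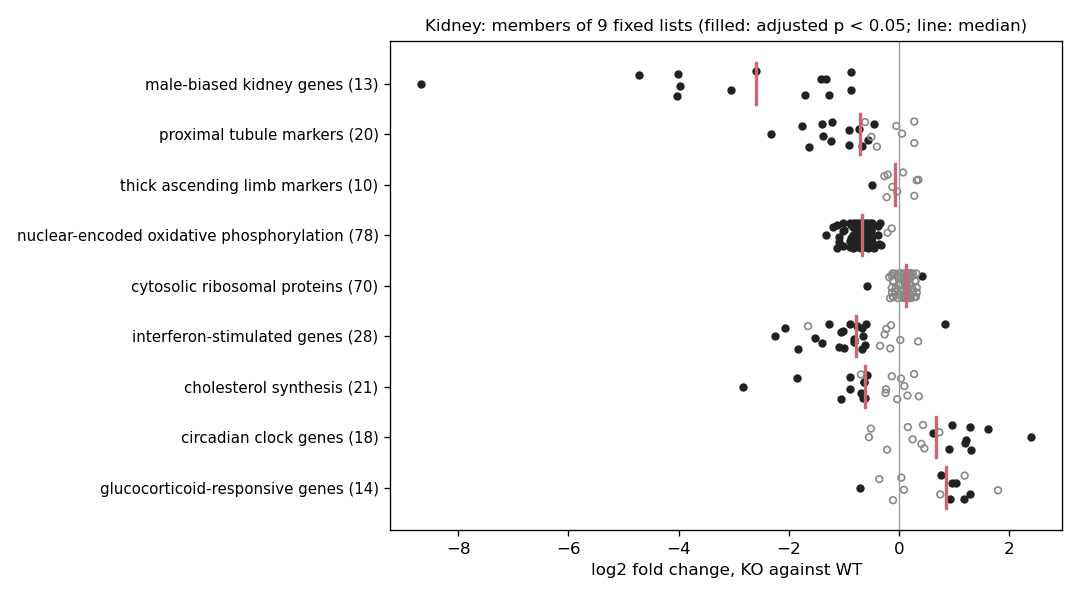
Log2 fold changes in kidney, KO against WT, for each tested member of 9 gene lists, with filled points for adjusted p below 0.05, open points for the rest and a line at each list's median. The male-biased genes have a median of -2.60 and the oxidative phosphorylation genes one of -0.67, while the 70 ribosomal protein genes have one of 0.12.

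Part of the cholesterol synthesis, interferon, macrophage and lymphocyte lists fell. Of 21 cholesterol synthesis genes, 11 fell (adjusted over the list alone, 11; camera adjusted p = 0.000282, and adjusted p = 0.485 with an estimated correlation), led by Cyp51, from 255 ± 48.0 to 35.6 ± 14.9 CPM, and Idi1, from 24.3 ± 7.48 to 6.70 ± 2.25 CPM. Of 28 interferon-stimulated genes, 19 fell and 1 rose (adjusted over the list alone, 20 and 1; camera adjusted p = 9.54e-07, and adjusted p = 0.479 with an estimated correlation), with Stat1 going from 16.2 ± 2.97 to 7.63 ± 0.555 CPM and Oas1a from 4.18 ± 0.717 to 1.46 ± 0.397 CPM. Macrophage markers fell in 9 of 17 cases (adjusted over the list alone, 9; camera adjusted p = 0.000787, and adjusted p = 0.508 with an estimated correlation), among them the complement genes C1qc (-0.99) and C1qa (-0.96). Lymphocyte markers fell in 6 of 16 cases (adjusted over the list alone, 6; camera adjusted p = 0.0217, and adjusted p = 0.485 with an estimated correlation), with Nkg7 at -3.05. Nkg7 levels were low, at 0.432 to 1.86 CPM in WT and 0 to 0.383 CPM in KO kidneys, so the size of its fall is uncertain. With a filter of at least 1 CPM in 6 libraries the lymphocyte list did not pass camera (adjusted p = 0.508). By plain library size, the summed lymphocyte markers overlapped (18.2 to 33.4 CPM in WT, 17.5 to 26.4 CPM in KO). The summed macrophage markers did too (162 to 330 CPM in WT, 147 to 254 CPM in KO). The summed neutrophil markers stood at 74.1 CPM in kidney WT 4 and at 3.09 to 4.53 CPM in the other WT kidneys, and adipocyte markers at 4150 CPM against 228 to 610 CPM.

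Part of the clock, glucocorticoid-responsive and immediate early lists rose. Of 18 circadian clock genes, 9 rose (adjusted over the list alone, 9; camera adjusted p = 0.00125, and adjusted p = 0.421 with an estimated correlation), including Cry1, from 2.79 ± 1.25 to 14.8 ± 7.20 CPM, and Cry2, from 17.3 ± 6.03 to 39.7 ± 4.29 CPM. The labels give no time of day for the dissections. Of 14 glucocorticoid-responsive genes, 6 rose and 1 fell (adjusted over the list alone, 7 and 1; camera adjusted p = 0.00785, and adjusted p = 0.485 with an estimated correlation), with Tsc22d3 at 1.03 and Sgk1 at 1.18. Of 15 immediate early genes, which also respond to tissue handling, 7 rose (adjusted over the list alone, 9), with Fosl2 at 1.30 and Junb at 1.04. Camera gave that last list adjusted p = 0.0076, adjusted p = 0.715 with an estimated correlation, and adjusted p = 0.0594 with plain library-size scaling.

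Across the kidney transcriptome, 6336 of 17376 genes changed in edgeR at an adjusted p below 0.05, of which 3064 rose and 3272 fell, and 1305 of them did so by at least 2-fold. Groups did not overlap for 2881 genes, or 16.6%, where chance gives 0.216%. For every kidney gene named above with a passed test, all 6 KO libraries lay on the stated side of the WT mean. The naming rule fixed this for the largest changes, and a small p made it likely for the rest, so it is no separate evidence. Plain library-size scaling moved the median over all genes from 0.03 to 0.32, and 82.4% of the genes called then rose, against 48.4% with TMM. Kidney changes therefore hold relative to the bulk of transcripts. The 10 most abundant genes took 25.1 ± 3.01% of counts in WT and 19.3 ± 1.56% in KO kidneys. In 1 fit of all 24 libraries, which shares the spread between the tissues, 3252 genes passed. Slc20a1, Fgfr1, Phlda1, Trpm7, Cldn10, Thsd7a, Wt1, Mafb, C1qa, Rpl13a, Rps4x and Slco1a6 did not pass there.

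The muscle comparison asks what changes in a tissue that makes little Kl. Among genes with a mean of at least 2 CPM, groups that do not overlap and an established symbol, the largest rise was that of Igf2, the fetal growth factor, at 3.33 ± 3.76 CPM in WT and 57.2 ± 11 CPM in KO muscle (log2 fold change 4.10). Muscle WT 4 alone stood at 10.9 CPM (other WT 1.04 to 2.44 CPM), and without it the log2 fold change was 4.98. Its adjusted p = 0.000353 came from edgeR quasi-likelihood with Benjamini-Hochberg adjustment, as throughout this comparison. Of the enzymes of polyamine metabolism, Amd1, the S-adenosylmethionine decarboxylase, fell from 1019 ± 397 to 60.1 ± 19.7 CPM (-4.08, adjusted p = 5.22e-06), and the spermine oxidase Smox from 538 ± 126 to 81.9 ± 18.0 CPM (-2.71, adjusted p = 5.37e-06). Nmrk2, a nicotinamide riboside kinase of muscle, fell from 213 ± 178 to 10.4 ± 4.58 CPM (-4.36, adjusted p = 0.000214). Chrna1, the acetylcholine receptor subunit that rises after denervation, went from 16.5 ± 2.06 to 43.5 ± 8.65 CPM (1.40, adjusted p = 0.000214).

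The other large rises in muscle were Gabrr2 (3.64), Stum (3.62), the acetylcholine receptor subunit Chrna9 (3.58, and 4.91 without muscle WT 4), the interleukin-6 receptor Il6ra (3.44), Adamts8 (2.98), the sestrin Sesn1 (2.84) and Abca4 (2.54). Falls included Actr3b (-4.02), Amd2 (-3.93), the ion channel genes Cacna2d4 (-3.88) and Kcng4 (-3.50, and -4.30 without muscle KO 3), and the zinc transporter Slc30a2 (-2.52). The rule that picked these genes admitted only those whose groups do not overlap, and KO values ranged widely for Sesn1 (137 ± 127 CPM) and Il6ra (33.8 ± 26.4 CPM). Amd2 is a near-copy of Amd1, so its counts may be reads of Amd1 and its level is uncertain.

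**Figure D3:**
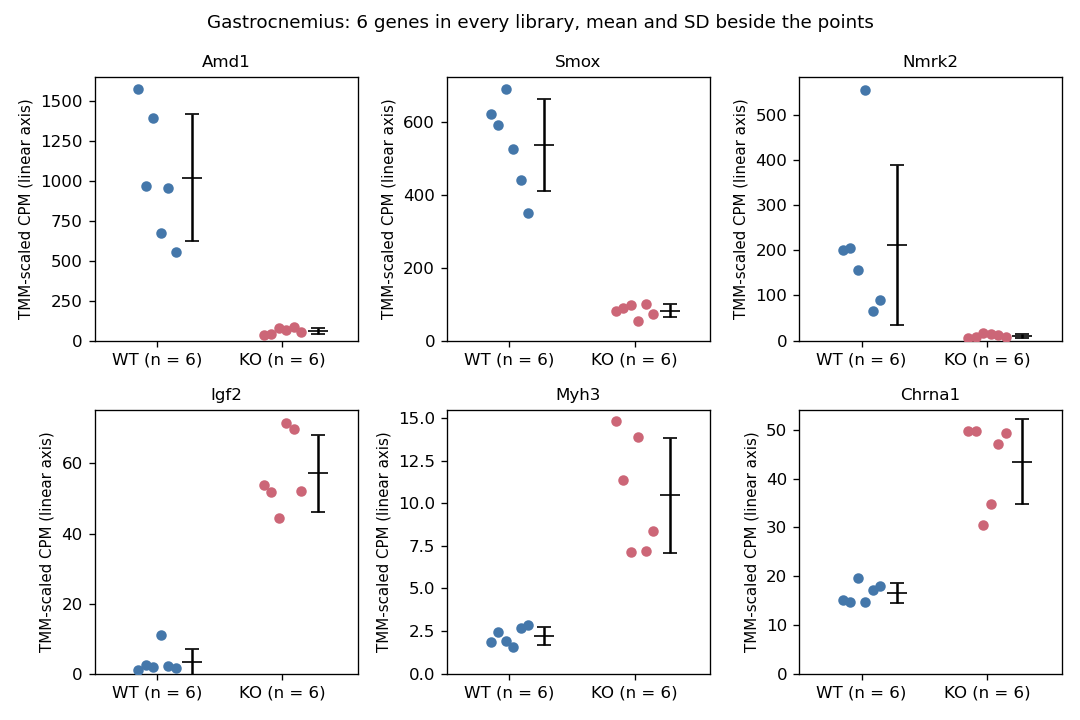
Amd1, Smox, Nmrk2, Igf2, Myh3 and Chrna1 in each gastrocnemius library, in TMM-scaled CPM on linear axes, with the mean and SD of each group beside its 6 points. Amd1 averages 1019 CPM in WT and 60.1 CPM in KO, and Igf2 3.33 and 57.2 CPM.

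Few members of the muscle lists passed singly. Of 12 polyamine genes, 3 fell and 1 rose (adjusted over the list alone, 4 and 1; camera adjusted p = 4.71e-07, and adjusted p = 0.188 with an estimated correlation). The median log2 fold change of this list was -0.245 and its mean -0.903. Amd2 was counted as a separate member, though its counts may be reads of Amd1. Amd1, Amd2 and Smox fell and Azin2 rose (0.85, edgeR adjusted p = 0.0395), the last not without any 1 of muscle WT 2, 3 or 6 or KO 1, 2, 4, 5 or 6 (highest adjusted p = 0.103). Of 15 genes of the IGF axis, 4 rose (adjusted over the list alone, 6 rose and 3 fell; camera adjusted p = 0.0463, and adjusted p = 0.528 with an estimated correlation). These were Igf2, the binding protein Igfbp3, from 18.4 ± 5.69 to 44.3 ± 16.5 CPM, the receptor Igf1r, from 14.5 ± 7.25 to 40.6 ± 15.5 CPM, and Igfals (0.64). Without muscle WT 3 or 4 or KO 1, 2 or 6, Igf1r did not pass (highest adjusted p = 0.0621), nor with no filter on low counts (0.0564). Igfals did not without any 1 of 10 libraries (all but WT 5 and KO 3, highest 0.108). The list as a whole did not without WT 1, 2 or 6 or KO 1, 4 or 5 (highest 0.0878). Of 16 denervation-responsive genes, Chrna1, Chrnb1 (0.81) and Ankrd1 (1.42) rose (adjusted over the list alone, 3). For this list, camera gave adjusted p = 0.00275, and adjusted p = 0.528 with an estimated correlation. Chrnb1 was lost without any 1 of muscle WT 2, 4 or 6 or KO 1, 2, 5 or 6 (highest adjusted p = 0.0886), and Ankrd1 without WT 2, 3, 4 or 6 or KO 1, 5 or 6 (highest 0.0748).

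Atrophy and developmental genes rose in part. Of 24 atrophy genes, 3 rose (adjusted over the list alone, 4; camera adjusted p = 3.51e-05, and adjusted p = 0.644 with an estimated correlation). They were the transcription factor Foxo3, from 22.8 ± 7.16 to 72.2 ± 29.1 CPM, Eif4ebp1, a brake on translation, from 49.7 ± 18.7 to 188 ± 105 CPM, and the protease gene Ctsl (1.01). Ctsl did not pass without any 1 of muscle WT 2, 3, 4 or 6 or KO 1, 2, 5 or 6 (highest edgeR adjusted p = 0.127). The ubiquitin ligases Trim63 and Fbxo32, singled out after their values were seen because they define this program, had log2 fold changes of 1.05 (edgeR adjusted p = 0.143) and 1.18 (adjusted p = 0.223). Of 12 embryonic and regeneration genes, 1 rose, the embryonic myosin Myh3, from 2.21 ± 0.519 to 10.5 ± 3.39 CPM (edgeR adjusted p = 9.9e-05; adjusted over the list alone, 2 rose). Its camera test gave adjusted p = 0.00374, and adjusted p = 0.528 with an estimated correlation. Of 13 glucocorticoid-responsive genes, Fkbp5 (1.6) and Cebpd (2.31) rose (adjusted over the list alone, 6 rose and 1 fell). Tested as a whole, it had adjusted p = 0.0124, and adjusted p = 0.644 with an estimated correlation. Fkbp5 was lost without any 1 of muscle WT 1, 2, 3 or 6 or KO 1, 2 or 6 (highest adjusted p = 0.0886), Cebpd without WT 1, 2, 3, 5 or 6 or KO 1, 2 or 6 (highest 0.103), and the list without KO 1 (0.0856).

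Of 24 interferon-stimulated genes in muscle, 4 fell (adjusted over the list alone, 8; camera adjusted p = 7.07e-07, and adjusted p = 0.528 with an estimated correlation). They were Ifi35 (-1.53), Isg15 (-1.69), Bst2 (-1.25) and Usp18 (-1.69). Bst2 was lost without muscle KO 2 or KO 6 (highest edgeR adjusted p = 0.0632), and Usp18 without WT 3 or 4 or KO 1, 2, 5 or 6 (highest 0.0724). Of 24 glycolysis and glycogen genes, Phka1, a phosphorylase kinase subunit, fell from 897 ± 237 to 413 ± 85.9 CPM (adjusted over the list alone, 6 fell). Camera gave it adjusted p = 0.00497, and adjusted p = 0.528 with an estimated correlation. Of 7 erythroid markers Alas2 rose (1.49, edgeR adjusted p = 0.0487; adjusted over the list alone, 6 rose; camera adjusted p = 0.00275, and adjusted p = 0.528 with an estimated correlation), a call that 10 of the 12 libraries carried (all but WT 5 and KO 1, highest adjusted p without 1 of them 0.0993). Camera also called 4 lists in which 0 genes passed singly. They were 79 oxidative phosphorylation genes (median -0.42; adjusted p = 0.0126, and adjusted p = 0.926 with an estimated correlation), 14 endothelial markers (-0.54; 0.0126 and 0.788), 70 ribosomal protein genes (0.38; 6.47e-08 and 0.788) and 13 slow fibre genes (0.83; 0.00204 and 0.644). Adjusted over the list alone, 0 members passed in these lists but for 1 slow fibre gene that rose. The oxidative phosphorylation call ended without muscle WT 1, 2 or 6 or KO 5 (adjusted p = 0.93 without WT 1) and the endothelial one without WT 5 (adjusted p = 0.194). Summed slow fibre transcripts stood at 4450 CPM in WT 6 and at 376 to 1080 CPM in the other WT muscles.

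In total, 730 of 14800 genes changed in muscle in edgeR, 303 up and 427 down, 430 of them by at least 2-fold, and groups did not overlap for 502 genes (3.39%, where chance gives 0.216%). For every muscle gene named above with a passed test, all 6 KO libraries lay on the stated side of the WT mean, except for Cebpd and Ctsl (5 of 6 each). As in kidney, the choice of genes fixed or favoured this, so it is no separate evidence. With plain library-size scaling 831 genes passed, 211 up and 620 down (25.4% up, against 41.5% with TMM), and the median over all genes moved from -0.04 to -0.14. The count with TMM depends on single libraries: it was 406 without WT 3, 1404 without WT 5, 361 without KO 1, 313 without KO 2, 444 without KO 5 and 313 without KO 6. WT 1 and WT 5 lay apart from the other muscle libraries and at opposite ends of the relation to transcript length (Spearman rho across genes -0.709 and 0.498). In all, 1277 genes passed without both, 1164 with the length trend removed, 1432 in DESeq2, 1805 in limma-voom and 2229 in 1 fit of all 24 libraries. With the replicate number as a block 494 passed. There Azin2, Igfals, Ctsl, Cebpd and Alas2 did not (edgeR adjusted p = 0.0877, 0.0728, 0.0917, 0.129 and 0.0515), nor did the IGF axis list (camera adjusted p = 0.0636).

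**Figure D4:**
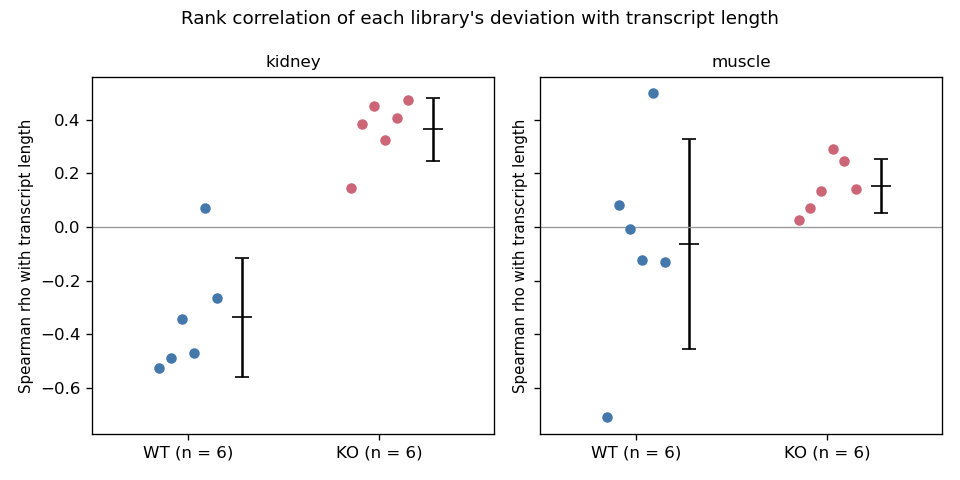
Spearman rank correlation, across genes, of each library's deviation from the tissue mean with transcript length, for kidney (left) and muscle (right), with the mean and SD of each group beside its 6 points. KO kidneys lie between 0.146 and 0.472 and WT kidneys between -0.526 and 0.072, while muscle WT 1 (-0.709) and WT 5 (0.498) lie apart.

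Whether loss of Kl acts differently in the tissues was tested as the interaction of tissue and genotype. The calcium channel subunit gene Cacna2d4 rose in kidney (log2 fold change 2.11) and fell in muscle (-3.88), an interaction of -5.96 (edgeR adjusted p = 4.54e-05; -6.73 without animal WT 2). Its kidney levels were low, at 0.118 ± 0.16 CPM in WT, where 4 of 6 libraries had 3 counts or fewer, and 0.532 ± 0.18 CPM in KO. Arc, an activity-dependent gene, likewise rose in kidney (1.25) and fell in muscle (-3.79, to 0 to 10 counts per KO library; interaction -5.04, adjusted p = 3.66e-05), and Ctxn3 fell in kidney (-2.92) and rose in muscle (2.12; interaction 5.02, adjusted p = 0.000439). Kl also passed (interaction 7.34, adjusted p = 1.49e-07). From 0.812 CPM in WT muscle, a fall to the floor of 3 counts over the KO group would be 6.05 on the log2 scale. A fall of 10.20, as in kidney, could therefore not have been seen in muscle. The fall seen there was 2.86, with 27 counts in sum over the KO muscles, so it did not reach that floor. What the remaining counts in KO muscle come from was not tested. Slc22a7 fell in kidney with muscle levels of 0.0583 CPM at most in either group mean. Foxq1, Folh1, Akr1d1, Sall1, Pkhd1, Tnk1 and Cdhr5 stood at 0 counts in one muscle group, so no fold is given for these genes in muscle.

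Of 18950 genes, 866 passed this interaction test in edgeR, 439 with a higher and 427 with a lower effect in muscle. Of these, 574 were called in kidney, 226 in muscle, and 40 in both with opposite signs. With the animal as a block 752 genes passed, and Slc22a7, Foxq1, Akr1d1, Pkhd1, Tnk1 and Cdhr5 did not (adjusted p = 0.0644, 0.0833, 0.148, 0.151, 0.1 and 0.109). In limma-voom Akr1d1, Folh1, Foxq1, Sall1, Pkhd1 and Tnk1 did not pass (adjusted p = 0.381, 0.323, 0.2, 0.0889, 0.0758 and 0.0655), nor did Slc22a7, Pkhd1 and Foxq1 in edgeR with no filter on low counts (0.0835, 0.061 and 0.0505). With counts divided by 2, Akr1d1, Cdhr5, Folh1, Pkhd1, Slc22a7 and Tnk1 did not pass (edgeR adjusted p = 0.0763, 0.068, 0.0935, 0.0609, 0.0879 and 0.0527). Leaving out 1 animal ended the calls of Slc22a7 (WT 2 or 5 or KO 2 or 3, highest adjusted p = 0.217), Foxq1 (WT 3 or 5 or KO 1 or 2, 0.055), Akr1d1 (WT 1, 2, 3, 5 or 6 or KO 1, 3 or 4, 0.111), Folh1 (WT 1, 3 or 4 or KO 3 or 6, 0.0663), Pkhd1 (all but WT 1, 4 and 5, 0.0898) and Cdhr5 (KO 2, 0.051). Counts without 1 animal moved past 1.5-fold for WT 1 (1316), WT 3 (528), KO 1 (542), KO 2 (526) and KO 6 (486). Plain library-size scaling gave 3173 genes, 7.72% of them higher in muscle against 50.7% with TMM, with the median over all genes at -0.44.

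Genes changed in both tissues were then compared. Of 13782 genes tested in both, 111 rose in both, where independent lists of the same sizes would share 50.3, and 137 fell in both, where 76.6 would. Stc2, a secreted glycoprotein hormone linked to calcium and phosphate, rose in kidney (1.87) and muscle (2.44; edgeR adjusted p = 9.62e-05 and 1.5e-05), as did the cold-inducible RNA-binding protein Rbm3 (1.06 and 1.40), Tfdp2 (0.68 and 2.14), Il6ra (0.92 and 3.44) and the TNF receptor family member Eda2r (2.14 and 2.25). Besides Kl, the anion exchanger Slc26a6 fell in both (-0.90 and -1.13), with Ifi35 (-0.66 and -1.53), Creld1 (-0.45 and -0.85) and the serine protease Hpn (-0.58 and -0.92). The interaction test put the larger effect in muscle for Tfdp2 (adjusted p = 0.00529), Il6ra (0.0112, but 0.0592 with the animal as a block and 0.171 in limma-voom) and Ifi35 (0.0276, but 0.0926 with no filter on low counts, 0.0556 in limma-voom, and lost without any 1 of WT 3 or 5 or KO 1, 2, 3, 4 or 6, highest 0.0777). In kidney, Creld1 and Hpn did not pass with plain library-size scaling (edgeR adjusted p = 0.196 and 0.0673).

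Opposite changes were fewer than independent lists would share. Rises in kidney with falls in muscle numbered 26 (expected 75.3), among them Smtnl2 (0.66 and -1.25), Cuedc1 (0.37 and -0.90), the translesion polymerase Polk (0.42 and -1.74), Arc, and the N-myristoyltransferase Nmt2 (0.30 and -1.08). Falls in kidney with rises in muscle numbered 14 (expected 51.2), among them Armh4 (-1.01 and 2.11), the sulfate transporter Slc13a4 (-2.63, or -3.29 without kidney KO 3, and 2.95), Nxpe3 (-0.67 and 2.07), Ctxn3 and Spns3 (-1.28 and 1.88). WT muscles had only 1 to 6 counts of Slc13a4 (0.0226 to 0.136 CPM), so the size of its rise is uncertain. Because these 10 genes were chosen for passed changes of opposite sign, an interaction was nearly bound to pass. It did for each in edgeR, with adjusted p from 5.84e-07 (Polk) to 0.000663 (Spns3). The kidney change did not pass for Nxpe3 with plain library-size scaling (edgeR adjusted p = 0.0551) or for Nmt2 with the length trend removed (0.0724). With no filter on low counts, kidney Spns3 (edgeR adjusted p = 0.0624), kidney Nmt2 (0.0632) and muscle Ctxn3 (0.0512) did not pass. Il6ra, Nmt2, Nxpe3 and Polk did not pass in kidney in 1 fit of all 24 libraries. The tissues came from the same animals, so chance differences between animals are shared by both lists. In muscle too the log2 fold change rose with transcript length, in the same direction as in kidney. Spearman rho was 0.137 over 14540 muscle genes, and 0.259 over the 7299 above 8 CPM. The overlap was not counted again with this trend removed, so how much of it follows the trend was not tested. The 248 genes of like direction became 510 with DESeq2 and 144 with the replicate number as a block. At an adjusted p below 0.01 they were 28, of which 16 rose in both (expected 5.82) and 12 fell in both (expected 10.5), so the excess of shared falls was small at that threshold.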

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

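Tests of a lower share of proximal tubule cells were chosen only after the results were seen, as was the removal of the trend over transcript length; and the rules that decide the cell-share test of oxidative phosphorylation and the Kl-neighbour test were made stricter after their first output.

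The fall of oxidative phosphorylation genes in KO kidney (median log2 fold change -0.67) was weighed against properties of the list, scaling and cell shares. Against gene length, GC content and expression level of the list as the whole cause, 0 of 100 matched random lists had a median as low (they ran from -0.62 to -0.25; with the length trend removed the list's median was -0.46 and 67 of 78 genes still fell), though the matched lists' own middle value of -0.41 leaves part of the fall to these properties. Against the choice of scaling, the highest median over 3 other scalings was -0.38. A lower share of proximal tubule cells cannot be told apart from a change within cells. The 51 markers of other segments and podocytes had a median of 0.0259 (bootstrap interval over genes -0.15 to 0.18), but 0.30 (0.14 to 0.47) with plain library-size scaling. A change of mitochondrial content within KO tubule cells, and a difference in RNA integrity, which the labels do not give, stay open and were not tested.

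The fall of male-biased genes in KO kidney (median -2.60) was weighed against cell shares, sex and scaling. A lower share of proximal tubule cells, if all were lost alike, is argued against as the whole cause. The male-biased median lay -1.90 from that of the proximal tubule markers (bootstrap interval over genes -3.45 to -0.36). That interval leaves out the spread between animals, and a loss of only part of these cells was not tested. Female animals are argued against by Y-linked genes summing to at least 112.8 CPM in every KO kidney, with Xist at most 0.37 CPM, and the highest median over 3 other scalings was -2.30. Lower androgen signalling in KO males may be a candidate explanation; no hormone was measured, so it stays open and untested.

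Genes near Kl were examined because a knockout made in another strain may carry that strain's alleles around the locus. Of 53 tested neighbours, 50 on one side and 3 on the other, 0 were called in both tissues in 1 direction, against 247 of 13728 other genes (1.80%; two-sided Fisher exact p = 1 for passenger alleles from the strain in which the knockout was made). With so few neighbours the share could reach 6.72%, so passenger alleles cannot be told apart from none, and the bound set in advance, an exact p of 0.05 or more, was too weak to decide.

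The counts were set against 100 splits of the same samples, the real one included. Chance was excluded for the 6336 kidney genes, the 730 muscle genes and the 866 interaction genes. Each was reached by 1 split of 100, the real one, with at most 0, 2 and 1 in any other. The 248 genes shared in direction were also reached by the real split alone. Every other split called 0 kidney genes and so could share 0, which leaves the splits unable to judge the overlap. Splits do not address cohort or litter: WT and KO animal numbers lie in separate ranges with no litter given, so a cohort difference cannot be told apart from genotype. Chance was not excluded for the number of lists called. At least the 16 kidney lists were reached by 48 of 100 splits (highest other 25), and at least the 13 muscle lists by 34 (highest other 19). The camera calls at the preset correlation therefore carry little weight. Counts of genes within each list were not set against the splits, and members of a list can vary together. Such counts stand beside a share of 36.5% of all genes called in kidney and 4.93% in muscle, rises and falls together. For a count in 1 direction, 3064 genes rose and 3272 fell of 17376 in kidney. In muscle 303 rose and 427 fell of 14800.

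In 39 of 378 groups of 6 libraries tested, 1 library stood far from the other 5, where chance gives about 1 in 20; genes that vary together make these groups dependent, and some of the genes were added after their results were seen. Animal WT 4 gave 16 of the 39. In its kidney, Marc1 stood at 4.37 CPM (others 1.04 to 2.19), Prlr at 47.2 (15.1 to 25.7), Cyp4a14 at 364 (others at most 204), Krt20 at 0.776 (0.0607 to 0.298), C1qc at 26.5 (16.2 to 19.3), Rps4x at 511 (378 to 414) and Mafb at 13.6, below the others (16 to 17.3), and the summed adipocyte and neutrophil markers at 4150 and 74.1. In its muscle, Igf2 stood at 10.9 CPM (1.04 to 2.44), Stum at 1.92 (0.553 to 0.936), Chrna9 at 1.86 (0 to 0.301), Nmrk2 at 557 (65.9 to 206), Fkbp5 at 101 (17.9 to 47.1), Polk at 14.9 (10.7 to 11.8) and neutrophil markers at 13.1 (0.842 to 2.07).

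In other WT animals, Kl stood at 907 CPM in kidney WT 3 (others 497 to 600), Cry1 at 5.25 in kidney WT 6 (1.85 to 2.90) and Calr at 890 in kidney WT 1 (586 to 692). In muscle, Rpl12 stood at 549 in WT 1 (52.6 to 217), Alas2 at 3.01 in WT 5 (0.689 to 1.48), and Casq2 at 42.6 (11.8 to 22.7) and the slow fibre sum at 4450 (376 to 1080) in WT 6. Among KO kidneys, Prlr stood at 261 (92.0 to 141), Acadm at 506 (345 to 395), Ace at 121 (59.0 to 81.9) and Polk at 12.6 (10.6 to 11.3) in KO 5, Odc1 at 186 in KO 3 (141 to 155), and mt-Nd2 at 13000 (8540 to 9990), Hspe1 at 194 (138 to 156) and, below the others, Creld1 at 22.8 (26.7 to 27.9) in KO 4. Among KO muscles, KO 3 had Stum at 5.49, below the others (11.2 to 14.1), Cacna2d4 at 1.43 (0.217 to 0.624) and Kcng4 at 18.5 (1.77 to 4.70). KO 4 had Adamts8 at 19.8 (3.71 to 7.41), Emcn at 5.65 (2.78 to 3.55) and Chrnb1 at 33.7, below the others (49.7 to 58.4). Ifi35 stood at 2.58 in KO 5 (1.71 to 2.00) and Ankrd1 at 12.4 in KO 1 (2.98 to 6.27).

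Effects that differed between the tissues were picked out by the edgeR interaction test, as log2 of muscle minus kidney. Positive values were those of Kl (7.34), Slc13a4 (5.60), Ctxn3 (5.02), Spns3 (3.16), Armh4 (3.11), Nxpe3 (2.74), Il6ra (2.51) and Tfdp2 (1.45). Negative values were those of Cacna2d4 (-5.96), Arc (-5.04), Sall1 (-4.90), Tnk1 (-4.61), Polk (-2.16), Smtnl2 (-1.91), Nmt2 (-1.38) and Cuedc1 (-1.27). Fitted values that depend on counts at or near 0 in 1 group, so that their size is uncertain, were those of Kl and Arc (muscle KO), Slc13a4 (muscle WT) and Cacna2d4 (kidney WT). The same holds, for 1 or both muscle groups, for Slc22a7 (7.24), Foxq1 (5.70), Folh1 (4.88), Akr1d1 (4.74), Pkhd1 (-4.87) and Cdhr5 (-4.25), and for Sall1 and Tnk1. Ifi35 had -0.873. Leaving out 1 animal ended the calls of Slc22a7 (WT 2 or 5 or KO 2 or 3, highest adjusted p = 0.217), Foxq1 (WT 3 or 5 or KO 1 or 2, 0.055), Akr1d1 (WT 1, 2, 3, 5 or 6 or KO 1, 3 or 4, 0.111), Folh1 (WT 1, 3 or 4 or KO 3 or 6, 0.0663), Pkhd1 (all but WT 1, 4 and 5, 0.0898), Ifi35 (all but WT 1, 2, 4 and 6 and KO 5, 0.0777) and Cdhr5 (KO 2, 0.051).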

How the results depend on the processing

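Plain library-size scaling, counts divided by 2, removal of the length trend and the fits without pairs of libraries were chosen only after the data were seen. For the results below the cause was not tested, except that a fold requirement or a stricter threshold calls fewer genes by construction.

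Kidney gave 6336 genes, 1305 of them at least 2-fold, and 3252 in 1 fit of all 24 libraries. The counts of the other alternatives stayed within 1.5 times, and leaving out 1 library gave 5455 to 6380. Like counts did not always mean like genes. With the length trend removed 5282 genes passed, 4406 of them among the 6336. Plain library size gave 8236 genes, 4512 of them among the 6336. Muscle gave 730 genes, and 430 at least 2-fold, 1432 in DESeq2, 1805 in limma-voom, 2229 in 1 fit of all libraries, 1277 without WT 1 and WT 5 and 1164 with the length trend removed. Without 1 muscle library it gave 313 to 1404: 406 without WT 3, 1404 without WT 5, 361 without KO 1, 313 without KO 2, 444 without KO 5 and 313 without KO 6. The interaction gave 866 genes, 1478 in DESeq2, 1539 in limma-voom and 3173 with plain library size, and without 1 animal 486 to 1316: 1316 without WT 1, 528 without WT 3, 542 without KO 1, 526 without KO 2 and 486 without KO 6. The 248 genes shared in direction became 510 in DESeq2, 28 at an adjusted p below 0.01 and 144 with the replicate block. With an estimated correlation 0 lists passed in either tissue; without 1 library 15 to 20 lists passed in kidney and 11 to 18 in muscle.

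Directions reversed for few results. The interaction of Eda2r, which did not pass, was -0.00412 with the animal as a block, -0.291 with plain library size and -0.0138, -0.244 and -0.0566 without animal WT 2, WT 6 or KO 6, and that of Rbm3, which did not pass either, was -0.0367 with plain library size. The muscle oxidative phosphorylation list, with a median of -0.42, ran from -0.592 without WT 5 to -0.061 without WT 1, where camera turned upward (adjusted p = 0.93); it also did not pass without WT 2, WT 6 or KO 5 (lowest adjusted p 0.0659).

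Kl kept its direction and its side of the threshold throughout, from -10.44 to -10.01 in kidney and -3.08 to -2.61 in muscle without 1 library. Over the genes examined, alternatives other than leaving out 1 library kept the side of the threshold in 1854 kidney cases and lost it in 99, kept it in 1007 muscle cases, lost it in 43 and gained it in 56, and kept it in 231 interaction cases, lost it in 25 and gained it in 2. Depth limits genes near the floor of 0.0554 to 0.103 CPM for 3 counts. Simulated 1.5-fold changes were recovered in 43.3% of cases in kidney but 4.48% in muscle, with few genes changed in either simulation.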

Other observations

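Genes chosen only after their values were seen are Ighm, Cd3e, Igkc, Jchain and Cyp24a1, and so were their fits without each muscle library; the lists were planned.

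In kidney, of 30 matrix genes, 7 fell, 2 rose and 21 did not pass (adjusted over the list alone, 6 fell and 2 rose; camera adjusted p = 0.147), with Col15a1 at -1.43 and Lox at 1.59. Of 18 unfolded protein response chaperones, 8 fell and 2 rose (adjusted over the list alone, 8 and 2; camera adjusted p = 0.0257, and adjusted p = 0.715 with an estimated correlation), with Calr from 680 to 371 CPM; the list did not pass without kidney WT 3 or KO 2 (adjusted p = 0.068) or with plain library size (0.112). Of 9 erythroid markers, 4 rose (adjusted over the list alone, 4; camera adjusted p = 0.0217, and adjusted p = 0.698 with an estimated correlation), with Alas2 at 1.67, but the list did not pass without kidney KO 4 (0.0521) or with plain library size (0.0679).

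The kidney lists that follow did not pass camera. Of 24 antioxidant genes, 10 fell and 5 rose (adjusted over the list alone, 11 and 5; adjusted p = 0.0675), with Prdx1 at -1.06. Of 26 fatty acid oxidation genes, 8 fell and 4 rose (adjusted over the list alone, 9 and 4; 0.129), with Acadm at -1.09 and Ppargc1a at 0.51. Of 17 heat shock proteins, 6 fell and 2 rose (adjusted over the list alone, 6 and 2; 0.16), with Hspe1 at -1.03. Of 19 senescence genes, 5 rose and 5 fell (adjusted over the list alone, 7 and 5; 0.987), with Glb1 at -1.32 and Cdkn1a at 1.56, the latter higher in 5 of 6 KO libraries. Of 14 Wnt targets, 5 rose and 2 fell (adjusted over the list alone, 9 and 2; 0.123), with Axin2 at 1.28 and Myc at 0.97. Of 16 genes of the IGF axis, 4 rose and 2 fell (adjusted over the list alone, 4 and 3; 0.987), with the growth hormone receptor Ghr at -1.34. Of 18 tubular injury markers, 2 rose and 2 fell (adjusted over the list alone, 1 and 1; 0.62), with Clu at -0.97 and Krt20 at 2.62 (3.37 without kidney WT 4). Of 11 renin-angiotensin genes, 1 rose and 2 fell (adjusted over the list alone, 1 and 2; 0.987), with Ace at -1.34. Of 14 endothelial markers, 3 rose (adjusted over the list alone, 2; 0.206), with Flt1 at 0.68. In kidney, median and camera direction differed in sign for adipocyte markers (median -1.13, camera up), the FGF and ERK targets (median 0.02, camera down), calcium and magnesium transport (0.07, down), distal convoluted tubule markers (-0.05, up), intercalated cell markers (0.04, down) and renin-angiotensin genes (0.08, down). Mean and median differed in sign for vitamin D metabolism (0.07 and -0.48), the IGF axis (0.01 and -0.12), calcium and magnesium transport (-0.14 and 0.07), renin-angiotensin genes (-0.14 and 0.08) and intercalated cell markers (-0.03 and 0.04). Cyp24a1, the enzyme that degrades active vitamin D, had a log2 fold change of 0.12 in edgeR (adjusted p = 0.83).

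In muscle, Ighm, an immunoglobulin heavy chain, had 1344 to 4347 counts in WT and 28 to 169 in KO libraries (log2 fold change -4.86, edgeR adjusted p = 7.89e-06, and at most 6.08e-05 without any 1 library). In kidney Ighm also fell (-0.89, edgeR adjusted p = 0.0029), but Igkc (-0.374, adjusted p = 0.473) and Jchain (-0.382, adjusted p = 0.587) did not pass. Summed lymphocyte markers in kidney overlapped, at 18.2 to 33.4 CPM in WT and 17.5 to 26.4 CPM in KO by plain library size. The T cell gene Cd3e fell in kidney (-1.30, edgeR adjusted p = 0.00862) and in muscle (-2.24, adjusted p = 0.0121, and at most 0.0347 without any 1 library). Lymphocyte markers in muscle summed to 32.3 to 92.1 CPM in WT and 1.23 to 5.21 CPM in KO, but most of this is Ighm: without it the sums were 1.26 to 2.84 and 0.57 to 1.48 CPM, which overlap. The plasma cell transcripts Igkc (2 to 13 counts in WT, 0 to 14 in KO) and Jchain (6 to 12 and 4 to 7) were too low to be tested there.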
